A study of Mus musculus with 8 samples.

How the data were processed

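Hearts of male mice on standard chow, 4 wild-type and 4 Gpihbp1 knockout, were profiled by RNA sequencing. Per the labels' protocols, RNA was extracted with TRIzol, polyadenylated RNA was selected, and strand-specific libraries made with dUTP were read as paired ends on a DNBSEQ instrument. One protocol paragraph of the labels names rat tissue; the organism given for every sample is mouse, and 17072 of the 17190 gene identifiers in the table matched mouse genes of the NCBI table for assembly GRCm38.p6. The submitters' processing notes name HISAT, Bowtie2 and the genome build GRCm39, without versions or the role of each; the counting program is not given in the sources used here.

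The authors deposited 1 table for the whole series. Per the file headers it holds estimated read counts (expected counts), TPM and FPKM for each library, and 8 further per-sample columns that were empty were not used. Between 4.32% and 5.89% of the count values of a library were not whole numbers, as estimated counts need not be. The TPM and FPKM values deposited by the authors were read but entered no test. Each row named a gene, no symbol occurred more than once, and 0 mitochondrially encoded genes were listed. Estimated counts can divide reads between genes that share sequence, so values of gene copies such as H3c14 and H3c15 depend on that division. Coordinates are not printed, because the reference in use here is of another build; it served for gene names and the order of neighbouring genes.

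Groups and replicate numbers were taken from the sample titles. Estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 12826. The comparison was fitted with edgeR 4.0.16 in R 4.3.3, with TMM scaling and the robust quasi-likelihood F-test without covariates, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors are the log2 fold change divided by the root of the F statistic, and CPM values are scaled by TMM. The choices of test, samples, gene lists, named genes and alternatives were fixed before the data were examined, except where a choice is said to have been made after seeing the data.

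Gene lists numbered 51: 5 had fewer than 5 tested members and 46 were tested. They covered cardiac metabolism, contraction, remodelling, stress and immune pathways, the circadian clock, ribosomal proteins, the chromosomal neighbours of Gpihbp1, mouse strain markers and the cell types a dissected heart could hold. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. For 9 lists, none past the threshold, the median, the mean and the direction of the test differed in sign. Named genes were Gpihbp1, 23 genes of lipid handling, remodelling and strain background chosen beforehand, and, of the genes past the threshold with a mean of at least 1 CPM whose groups did not overlap, the 10 with the smallest p and the 5 with the largest fold in each direction, excluding predicted gene names. A further part named up to 4 members past the threshold, in each direction, of every list that passed or held at least 3 such members. Among the genes chosen beforehand, 1 entered every test and count but is not reported here. Any other gene named was chosen after its values were seen. Members of lists that are named without passing serve as examples.

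Per-library totals and shares were compared by exact two-sided permutation over the 70 arrangements of 8 libraries; a mitochondrial share could not be computed, as no such gene was listed. The 95% interval of the Gpihbp1 ratio is an exact binomial one, and the floor for a group at 0 is 3 counts. This interval and the floors cover counting error at most, since amplified reads without molecular identifiers are not independent molecules. The 95% intervals of log2 fold changes were built from the standard errors of the quasi-likelihood fit, so they also include the spread between hearts. Library totals ranged from 9065553 to 13492957 counts, and the biological coefficient of variation was 43.7%. No 2 libraries agreed within sampling noise: the chi-square statistic per degree of freedom over genes was at least 7.59 for every pair.

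The fit was tested on simulated counts for this comparison, drawn from the means, dispersions and library sizes of the tested genes, with 200 genes changed, 50 at each size of change, all with a mean of at least 10 CPM. Of 12710 genes run, 96% of the 50 genes changed 8-fold were recovered, 76% of those changed 4-fold, 2% of those changed 2-fold and 0% of those changed 1.5-fold. Of 12510 unchanged genes 2 were called. In all 89 genes were called, so the adjustment let larger unadjusted p-values pass than with the 4 genes called in the real comparison. The recovered shares can therefore be too high for the real data, also at 4-fold and 8-fold. With no gene changed 0 genes and 1 of 46 lists passed, and a list of 30 genes moved 2-fold had an adjusted p of 1.77e-25. Genes were drawn independently of each other, whereas estimated correlations between members of the real lists reached 0.956. The simulation therefore does not check how the list test behaves on correlated genes at the preset correlation.

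Alternatives were RLE, upper-quartile or total-count scaling, DESeq2 1.42.0, limma-voom with and without quality weights, no filter (at least 1 count in all) and a strict filter (at least 50 counts in 4 libraries), each library left out in turn, the shared replicate numbers as a block, 1 surrogate variable from sva 3.50.0, an adjusted p under 0.01, glmTreat with a log2 fold of 0.5, and the quasi-likelihood fit without the robust option. After seeing the data, fits without wild-type 2 and knockout 2, without these and wild-type 6, with 2 surrogate variables, and with H3c14 and H3c15 counted as 1 gene were added.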

Results

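RNA sequencing of mouse hearts compared wild-type males with males lacking Gpihbp1, the endothelial protein that binds lipoprotein lipase and carries it to the capillary lumen, where it releases fatty acids from circulating triglyceride. Each group had 4 hearts, numbered 2, 4, 5 and 6 in the wild type and 1, 2, 3 and 4 in the knockout, and all mice ate standard chow. The table listed 17190 genes. Total counts per library ran from 9065553 in wild-type 4 to 13492957 in wild-type 2. The stated purpose was to learn what loss of Gpihbp1 does to the heart. The labels do not say whether the hearts came from littermates or were collected on 1 day, and give no batch, so the p-values measure the spread between these 8 hearts only.

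The targeted gene separated the groups completely. Gpihbp1 (NCBI gene 68453) had 1108, 1951, 833 and 1783 reads in wild-type 2, 4, 5 and 6, and 0, 0, 1 and 0 reads in knockout 1, 2, 3 and 4. The wild-type level was 146 ± 86.8 CPM (counts scaled to library size; SD, n = 4). Summed over the groups, 5675 wild-type reads stood against 1 knockout read, a ratio of 6188 after scaling for depth, with a 95% counting interval from 1110 to 244470. In edgeR's quasi-likelihood test the adjusted p was 0.000598. Every library therefore matched the genotype in its label.

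Beyond Gpihbp1, 3 genes passed the threshold, and all 3 were higher in the knockout. Arc (NCBI gene 11838), a cytoskeleton-associated immediate early gene best known from neurons, rose from 3.07 ± 0.714 to 44.1 ± 8.55 CPM (SD, n = 4 each), a log2 fold change of 3.85 with a standard error of 0.26 (edgeR adjusted p = 0.000598). Psca (NCBI gene 72373), a small cell-surface protein of the Ly6 family to which Gpihbp1 also belongs, rose from 0.208 ± 0.146 to 8.85 ± 3.07 CPM, with a log2 fold change of 5.45 and a standard error of 0.52 (edgeR adjusted p = 0.00691). Psca rested on 8 wild-type and 428 knockout reads. H3c14 (NCBI gene 15077), a replication-dependent histone H3 gene, was listed at 0 in all wild-type libraries and at 25 to 46 reads in the knockout libraries, which was at least 44.6-fold higher against a floor of 3 counts over the wild-type group (edgeR adjusted p = 0.0446). Its gene copy H3c15 had 27, 15, 15 and 13 reads in wild-type 2, 4, 5 and 6 and 0, 0, 0 and 8 in knockout 1, 2, 3 and 4, so the value for either copy alone is uncertain.

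**Figure D1:**
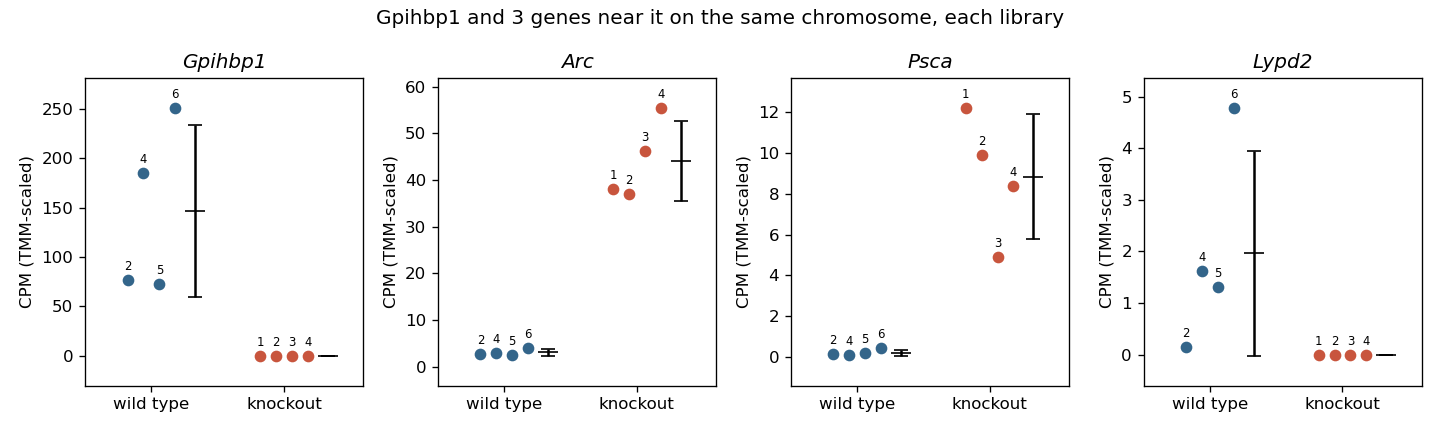
TMM-scaled CPM (linear axes) of Gpihbp1, Arc, Psca and Lypd2 in each library; points are single hearts numbered as in the labels, and bars give the mean and SD of 4. Arc lay at 36.9 CPM or more in every knockout heart and at 4.08 CPM or less in every wild-type heart.

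In all, 4 of 12826 tested genes differed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 3 higher and 1 lower, and each had a log2 fold change of at least 1 in size. At an unadjusted p under 0.05 there were 116 genes, 32 higher and 84 lower, where evenly spread p-values would give 641.3. Of the 35 splits of the 8 libraries into 4 and 4, 25 gave as many, the real grouping included. The other splits had a median of 374.5. The groups did not overlap for 34 genes higher and 47 lower in the knockout, together 0.632% of genes, against 2.86% by chance. Neither low count shows that the groups are alike. DESeq2 called 8 genes, the same 4 and Fbp2, Gm12816, Pde11a and Plbd1, and leaving out wild-type 4 or wild-type 5 left 2, Gpihbp1 and Arc, with edgeR adjusted p-values of Psca of 0.0716 and 0.0830. Arc stayed past the threshold in all 8 fits that left out 1 library and H3c14 in 0 of 8, with edgeR adjusted p-values of H3c14 from 0.0687 to 0.374. With Gpihbp1 left out before adjustment, 2 genes passed rather than 3, and with its listed neighbours left out as well 0 passed.

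Arc and Psca are both chromosomal neighbours of Gpihbp1. In the gene order of assembly GRCm38.p6, counted over genes the table listed, Arc lay 22 and Psca 20 places before Gpihbp1. Of the 51 neighbouring genes fixed as a list before the data were examined, 35 were tested, and Arc and Psca were the 2 that passed, over all genes and adjusted over the list alone. The list as a whole did not move one way: its median log2 fold change was -0.15, its mean 0.12, and the camera test gave an adjusted p of 0.780. Genes between and beside them, such as Jrk at 0.40 and Them6 at -0.17 on the log2 scale, had standard errors of 0.26 and 0.28 and did not pass. Neither did Lynx1 at -1.13 (standard error 0.49) and Top1mt at -1.01 (standard error 0.31), whose edgeR unadjusted p-values were 0.0454 and 0.00862 (adjusted p = 0.99998 for both). Lypd2, another Ly6 family gene 17 places before Gpihbp1, was below the count filter and was picked out after its values were seen. It had 2, 17, 15 and 34 reads in wild-type 2, 4, 5 and 6 and 0 in every knockout library, at least 24.7-fold lower against a floor of 3 counts over the knockout group; in the 8 alternative fits that tested it, its adjusted p was at least 0.619.

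**Figure D2:**
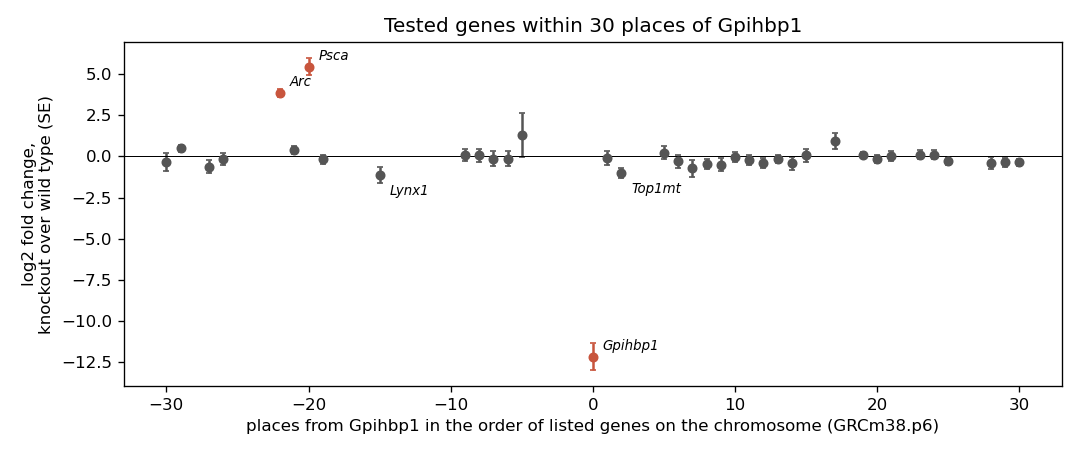
Log2 fold change (knockout over wild type, bars are 1 standard error) of each tested gene within 30 places of Gpihbp1, by its place in the order of listed genes on the chromosome. Gpihbp1, Arc and Psca, in red, passed the threshold; Lynx1 and Top1mt are named because their unadjusted p was under 0.05.

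Genes of lipoprotein lipolysis and fatty acid uptake other than Gpihbp1 did not pass the test. Lpl, the lipase that Gpihbp1 binds, stood at 4548 ± 1757 CPM in the wild type and 3726 ± 1564 in the knockout (SD, n = 4 each), with a 95% interval of its log2 fold change from -1.39 to 0.82. Cd36, the main fatty acid transporter of cardiomyocytes, had a log2 fold change of 0.0051 and an interval from -0.91 to 0.92. Fabp4, a fatty acid carrier of capillary endothelium, had -0.52 with an interval from -1.59 to 0.54. Angptl4, a secreted inhibitor of lipoprotein lipase, had 0.11, with an interval as wide as -2.88 to 3.10. Of 17 tested genes in the intravascular lipolysis list, Gpihbp1 alone passed, both over all genes and adjusted over the list alone, and 0 of 19 passed in the fatty acid uptake list. The camera test gave adjusted p-values of 0.308 and 0.893 for these lists.

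Genes of fuel choice did not pass over all genes. Pdk4, the kinase that restrains glucose oxidation, had -1.10 with an interval from -2.09 to -0.11 (unadjusted p = 0.0329, edgeR adjusted p = 0.99998). Without wild-type 5 it had -0.63 (unadjusted p = 0.118), and without wild-type 6, knockout 1 or knockout 2 the unadjusted p was 0.0646, 0.0869 and 0.0565. Cpt1b, which admits fatty acids to mitochondria, had -0.23, Ucp3 had -0.42 and the lipid droplet protein Plin2 had 0.11, each with an interval that spanned 0. The glucose transporter Slc2a1 had 0.37, with an interval from -0.73 to 1.47. Across the list of PPARα target genes, which holds Pdk4, Cpt1b, Ucp3, Plin2 and Angptl4, 0 of 31 tested members passed, likewise 0 adjusted over the list alone, and 23 had negative and 8 positive log2 fold changes. The camera test placed the list lower, with an adjusted p of 0.00732, and the adjusted p was 0.966 with an estimated correlation. Its call was lost without wild-type 5, wild-type 6 or knockout 2, with camera adjusted p-values of 0.596, 0.318 and 0.548; its mean without wild-type 5 or wild-type 6 was -0.24 and -0.17. The beta-oxidation list of 26 genes had a median of -0.10 and a camera adjusted p of 0.777, and the glycolysis list of 33 had 0.17 and 0.0832. Both passed in some fits that left out 1 library: beta-oxidation with a mean of -0.35 without wild-type 2 (0.000177) and 0.074 without knockout 2 (0.0247), and glycolysis, placed higher, without wild-type 6, knockout 1 or knockout 2 (6.24e-06, 0.0488 and 0.0147).

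**Figure D3:**
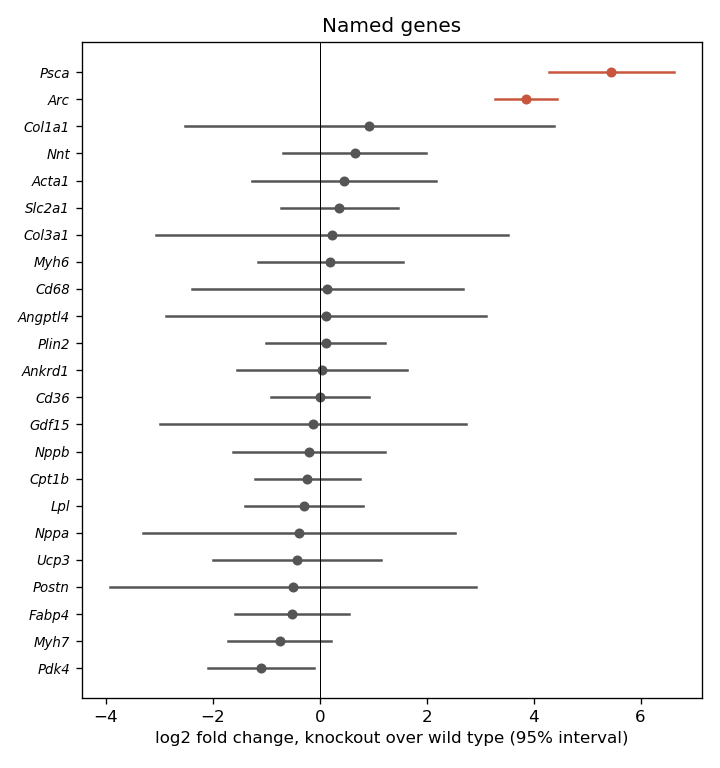
Log2 fold change (knockout over wild type) and its 95% interval for the genes named in the text other than Gpihbp1 and H3c14, ordered by size. Arc and Psca, in red, passed the threshold, and the interval of Pdk4, which did not pass after adjustment, lies below 0 with all 8 libraries in the fit.

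Markers of cardiac stress, fibrosis and inflammation did not pass the test between the genotypes, and their spread was large within both groups. The natriuretic peptide gene Nppa stood at 1692 ± 1739 CPM in the wild type and 1293 ± 2117 in the knockout, with an interval of its log2 fold change from -3.30 to 2.53. Nppb had -0.21, the fetal myosin Myh7 -0.74, the adult myosin Myh6 0.20, skeletal actin Acta1 0.45 and the stress-responsive Ankrd1 0.040 on the log2 scale, each with an interval spanning 0. The collagens Col1a1 and Col3a1 had 0.93 and 0.22, the matrix protein Postn -0.50, the stress cytokine Gdf15 -0.12 and the macrophage marker Cd68 0.14. Nnt, a mitochondrial transhydrogenase that some inbred mouse strains lack, was read in all libraries and had 0.65, with an interval from -0.68 to 1.99. The fasting hormone Fgf21 was not tested, with 5 wild-type and 2 knockout reads. Of the 23 genes named before the data were examined apart from Gpihbp1, 22 were tested and 0 passed, and 2 had an unadjusted p under 0.05. Their edgeR adjusted p was 0.99998.

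Much of this spread lay in 1 heart of each group. Wild-type 2 and knockout 2 stood at 3132 and 4467 CPM of Nppa, 1532 and 1069 CPM of Postn, 3607 and 4384 CPM of Col3a1 and 192 and 217 CPM of Cd68. In the other 6 libraries Nppa was also high in wild-type 6, at 3262 CPM, while Postn ran from 35.5 to 68.2, Col3a1 from 109 to 203 and Cd68 from 14.3 to 19.8 CPM. Both hearts were also lower in Cpt1b, at 331 and 386 CPM against 694 or more elsewhere. The first principal component, which carried 53.1% of the variance of log2 CPM, placed them at 86.2 and 81.0 and the other 6 libraries between -42.4 and -19.2. Wild-type 6 stood apart on the second component, with 24.2% of the variance, and alone held high levels of the atrial myosin light chain Myl4, at 974 CPM against 2.45 or less elsewhere. Without wild-type 2 and knockout 2, a fit chosen after seeing the data called 3 genes, Gpihbp1, Arc and Psca. Without wild-type 6 as well it called Gpihbp1, Arc and Fbp2.

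**Figure D4:**
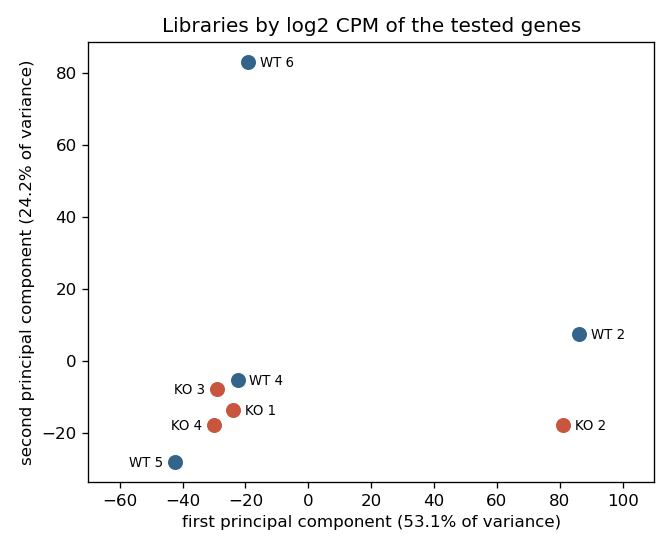
Libraries on the first and second principal components of log2 CPM of the tested genes; wild type in blue, knockout in red, numbered as in the labels. Wild-type 2 and knockout 2 lie together at 86.2 and 81.0 on the first component, and wild-type 6 lies alone at 83.0 on the second.

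**Figure D5:**
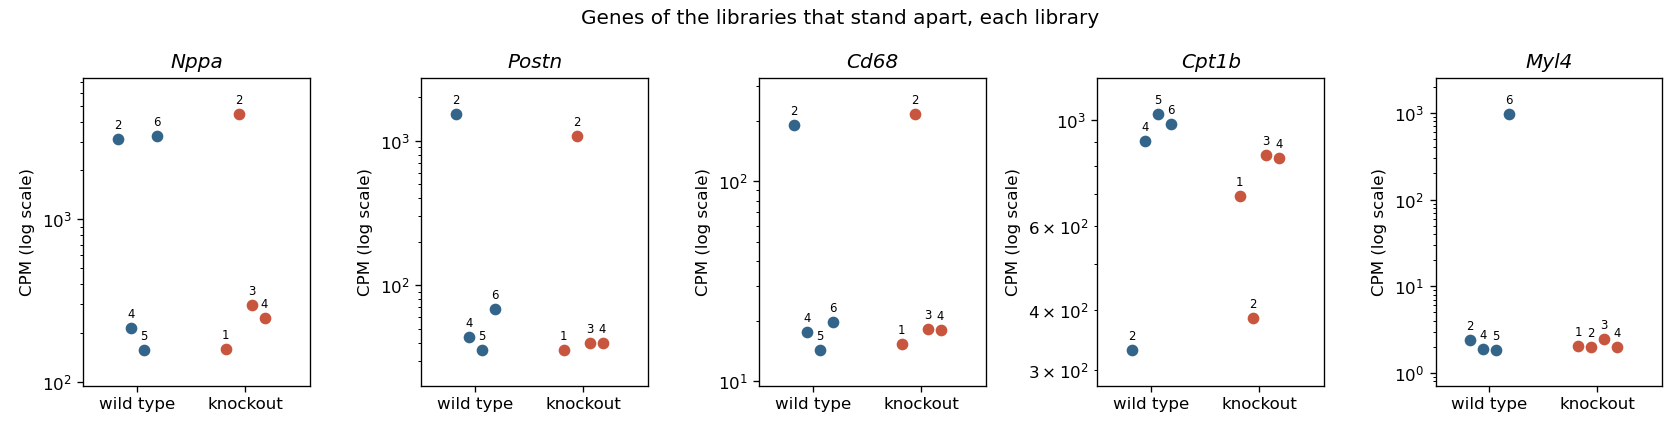
CPM of Nppa, Postn, Cd68, Cpt1b and Myl4 on log axes, 1 point per heart, numbered as in the labels. Nppa was high in wild-type 2, wild-type 6 and knockout 2, Postn and Cd68 were high and Cpt1b low in wild-type 2 and knockout 2, and Myl4 was high in wild-type 6.

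Among 46 gene lists fixed before the data were examined, the camera test placed 8 past the threshold, 5 lower and 3 higher in the knockout, and 0 of these 8 held a gene that passed, over all genes or adjusted over the list alone. With an estimated correlation the camera adjusted p was 0.966 for each of the 8, the same value as for every other of the 46 lists. In fry, which asks whether the genes of a list move one way on balance, 1 list passed, intravascular lipolysis, which holds Gpihbp1 (adjusted p = 0.00779). Its median log2 fold change was 0.0027, with 9 members positive and 8 negative. The fry call therefore does not show that members other than the deleted gene moved one way. Ribosomal protein genes were placed lower, with 67 of 67 negative and a mean log2 fold change of -0.997 (camera adjusted p = 4.23e-25). Wild-type 2 and wild-type 6 had the highest median deviation of this list, 0.92 and 1.64 in log2 units. Its call held in all 8 fits that left out 1 library (camera adjusted p at most 1.84e-08), with a mean of -0.48 without wild-type 6. Without wild-type 2, wild-type 6 and knockout 2 together its camera adjusted p was 0.743. Nuclear genes of oxidative phosphorylation had a mean of -0.59 (adjusted p = 3.53e-07), with wild-type 6 at 1.55; without wild-type 6 the mean was 0.070, without knockout 2 it was -0.40, and without it or without knockout 2 the call was lost, with adjusted p-values of 0.182 and 0.478. Cholesterol synthesis genes, such as Fdft1 at -0.61 and Cyp51 at -0.65, had a mean of -0.27 (adjusted p = 0.00732), which did not pass without wild-type 2, knockout 1 or knockout 2, with adjusted p-values of 0.751, 0.0887 and 0.0598, and had a mean of -0.061 without wild-type 2. Schwann cell and neuronal markers had a mean of -0.52 (adjusted p = 0.0416), lost without wild-type 4, wild-type 5, knockout 2 or knockout 3, with adjusted p-values of 0.505, 0.0640, 0.159 and 0.147, and with a mean of -0.22 without wild-type 4. RLE scaling (0.0583), no filter (0.0819) and the strict filter (0.439, mean -0.25) lost it too.

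The lists placed higher were neutrophil markers, interferon-response genes and clock genes, each again with adjusted p = 0.966 with an estimated correlation. The 7 tested neutrophil markers were all positive, with a mean log2 fold change of 1.25 (camera adjusted p = 0.00109); S100a8 stood at 8.67, 29.7, 25.1 and 0.754 CPM in knockout 1, 2, 3 and 4 and between 0.699 and 11.2 in the wild type. This call was lost without wild-type 5 or knockout 2, with adjusted p-values of 0.0640 and 0.116, and the mean was 0.33 without knockout 2, 2.22 without wild-type 2 and 1.98 without knockout 4. Interferon-response genes, such as Ifit2 at 0.71 and Ifi44 at 0.76, had a mean of 0.20 (adjusted p = 0.0136), which without knockout 2 was -0.23, and the call was lost without wild-type 5, knockout 1 or knockout 2, with adjusted p-values of 0.834, 0.299 and 0.977. Their mean was 0.62, 0.017 and 0.11 without wild-type 2, 5 and 6, and 0.40 and 0.34 without knockout 3 and 4. Total-count scaling also lost the call (0.0583, mean 0.31), as did the replicate block (0.869, mean 0.028). Clock genes had a mean of 0.33 (adjusted p = 0.0231), with Ciart at 1.95, Dbp at 1.06, Per2 at 0.94 and the activator Arntl at -0.90. Their call held in 3 of 8 fits that left out 1 library; it was lost without wild-type 2, wild-type 6, knockout 1, knockout 3 or knockout 4, with adjusted p-values of 0.318, 0.0791, 0.173, 0.0993 and 0.0574, and the mean was 0.22 without wild-type 2 and 0.52 without wild-type 5. The strict filter lost it as well (0.0776, mean 0.24). The other 38 lists had camera adjusted p-values from 0.0526 to 0.920, among them extracellular matrix and fibrosis at 0.282, the hypertrophic fetal program and adult sarcomere genes at 0.920, mouse strain markers at 0.136, inflammation at 0.0968, the unfolded protein response at 0.780 and the oxidative stress response at 0.780. These results also depended on single libraries: 26 of the 38 passed in at least 1 fit that left out 1 library, 7 of them in both directions. Extracellular matrix and fibrosis had a mean of 1.34 without wild-type 2 (0.000680), -1.48 without knockout 2 (1.60e-08) and -0.24 without wild-type 6 (0.00239). Inflammation was placed higher without wild-type 2, knockout 3 or knockout 4, with means of 1.14, 0.37 and 0.46 (2.97e-05, 0.0208 and 2.53e-05). Its mean over all fits that left out 1 library ran from -0.59 to 1.14. The hypertrophic program passed without wild-type 2 (0.33, 0.0488), adult sarcomere genes without wild-type 6 or knockout 2 (0.00876 and 0.0271) and the unfolded protein response without knockout 2 (-0.28, 0.0396). The mean of the hypertrophic program ran from -1.02 to 0.33 over the fits that left out 1 library.

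Markers of the other cell types of the heart were compared in the same way. Endothelial markers, which share their cell type with Gpihbp1, had a median log2 fold change of -0.066 over 24 genes (camera adjusted p = 0.777), cardiomyocyte markers -0.21 over 16 (0.549), fibroblast markers -0.11 over 21 (0.0968), mural cell markers -0.045 over 18 (0.777) and macrophage markers -0.40 over 27 (0.893). Adipocyte markers had -0.54 over 6 genes (0.0526) and erythroid and platelet markers -1.19 over 11 (0.134), with wild-type 6 highest in both lists. Several passed when 1 library was left out. Macrophage markers had a mean of 0.98 without wild-type 2 (0.000332) and -1.26 without knockout 2 (0.0163), and endothelial markers -0.36 without wild-type 2 (0.00128), -0.41 without knockout 1 (0.00909) and 0.29 without wild-type 4 (0.00536). Cardiomyocyte markers had -0.40 without wild-type 2 (0.00972) and fibroblast markers -0.20 without wild-type 6 (0.00727). Over all fits that left out 1 library the cardiomyocyte mean ran from -0.40 to 0.18 and the fibroblast mean from -0.80 to 0.66. Adipocyte markers passed as lower without wild-type 2, knockout 1 or knockout 3 (0.0481, 0.0259 and 0.0438), with total-count scaling (0.00997, mean -0.39) and without the filter (0.00147, mean -1.13). Without wild-type 6 the adipocyte mean was -0.26 and the list did not pass (0.123). Erythroid and platelet markers passed as lower without wild-type 4, wild-type 5 or knockout 3 (0.0133, 0.0109 and 0.0266) but had a mean of 0.23 without wild-type 6 and passed as higher (0.0247). None of 5 technical measures of the libraries passed a test between the groups. The ribosomal protein share of counts was 4.64 ± 2.48% in the wild type and 2.82 ± 0.960% in the knockout (exact two-sided permutation p = 0.257, n = 4 each), and the haemoglobin share was 0.265 ± 0.378% and 0.0756 ± 0.0296% (exact permutation p = 0.514, n = 4 each). Wild-type 6 stood at 0.825% haemoglobin and the other wild-type hearts at 0.0287% to 0.160%. Detected genes numbered 15230 ± 246 and 15359 ± 301 (exact permutation p = 0.514, n = 4 each). For total counts and the share of the 10 most abundant genes the exact permutation p-values were 0.886 and 0.743. The Benjamini-Hochberg adjusted values of these 5 measures were 0.857 and 0.886, and 4 hearts against 4 cannot give an exact p below 0.0286.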

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

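The tests of depth and of other splits of the libraries were fixed before their results were seen, except the splits without Gpihbp1, and the other tests in this part were chosen after the values were seen. Across 61 sets of 4 libraries (the named genes on the log2 CPM scale and the per-library measures), 15 had a library farther from the other 3 than Dixon's 95% limit, where chance gives about 3.05. Knockout 2 was the distant library for Angptl4 (86.1 CPM, others 1.96 to 3.01), Plin2 (227, others 53.2 to 67.5), Col1a1 (2905, others 58.0 to 104), Col3a1 (4384, others 109 to 203), Postn (1069, others 35.5 to 39.8), Gdf15 (45.3, others 2.15 to 3.49), Cd68 (217, others 15.4 to 18.3) and Cd36 (856, others 1460 to 1549), and for its total of 13443527 counts (others 10346930 to 10702540). Wild-type 2 was distant for Col3a1 (3607 CPM, others 146 to 194), Gdf15 (49.7, others 2.18 to 3.23), Cd68 (192, others 14.3 to 19.8) and Cpt1b (331, others 902 to 1028). Wild-type 6 had a haemoglobin share of 0.825% (others 0.0287% to 0.160%). Knockout 3 held the single knockout read of Gpihbp1, 0.0979 CPM.

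Wild-type 2 and knockout 2 stood apart from the other libraries in the same genes. Greater depth is argued against: they had the highest totals, but after every library was thinned to 9065553 counts the gap on the first component kept 99.9% of its size. A lower share of cardiomyocytes is argued against as the whole account, since it would raise every other cell type: the median deviations of endothelial markers were -0.89 and -0.65 in wild-type 2 and knockout 2 while those of macrophage markers were 2.33 and 1.53, a difference of 2.18 in the heart where it was smaller. A batch shared by the number 2 cannot be told apart from a property of these hearts, because the labels give no batch. Of the 2 pairs that share a number, number 2 had a deviation correlation of 0.908 and number 4 of 0.110, where hearts with different numbers ranged from -0.671 to 0.685. No biological explanation was tested, since the design gives no group that holds these 2 hearts.

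Arc and Psca rose in every knockout heart. A general induction of immediate early genes at dissection is argued against for Arc: the 24 other such genes had a median log2 fold change of -0.26 with an SD of 0.32 between them, far below the lower end of Arc's 95% interval, 3.27. Linkage to the targeted allele may account for both. Of the 3 called genes other than Gpihbp1, 2 lay among its 37 tested neighbours within 30 places (exact hypergeometric p = 2.43e-05). That test and its window were chosen after Arc and Psca were seen to pass, so its p-value is not independent support. In the neighbour list fixed beforehand, Arc and Psca were the 2 of 35 tested members that passed. Whether Arc and Psca rose through strain DNA that flanks the allele, through the targeting construct, or instead through the loss of Gpihbp1, stays open. All of these coincide with the genotype in this design.

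H3c14 was at 0 in every wild-type library, where H3c15 was read. Of 971 words of 50 bases in the H3c15 transcripts of GENCODE M21, 63.5% also occurred in those of H3c14, but of the 1776 words of H3c14 only 34.7% occurred in those of H3c15. Counted as 1 gene, the pair had 27, 15, 15 and 13 reads in wild-type 2, 4, 5 and 6 and 38, 46, 37 and 33 in knockout 1, 2, 3 and 4, a log2 fold change of 1.02 with a standard error of 0.30 (edgeR adjusted p = 0.99998), against 8.14 for H3c14 alone with a standard error of 0.70. Adding H3c15 reads to a wild-type count of 0 lowers the fold change whether or not the copies share reads, so this fall cannot decide the question. A division of shared reads between the copies that differs with genotype may account for part of the H3c14 value. Its share is unsettled because most H3c14 words are its own. A change of the pair by itself also stays open, with an edgeR unadjusted p of 0.00727.

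The number of genes past the threshold was larger in the real grouping, 4, than in any of the other splits of the 8 libraries into 4 and 4, whose highest was 0, so 1 of 35 splits gave as many. The design itself sets Gpihbp1 apart in the real grouping, so this total does not by itself exclude chance for other genes. With Gpihbp1 left out before adjustment the real grouping gave 2 genes and the highest of the others 0, so 1 of 35 splits gave as many. That is the smallest share 35 splits can give, and this count was chosen after the values were seen, so chance is not excluded. With its listed neighbours left out as well, the real grouping gave 0, as did the highest other. Since 35 of 35 splits must give at least 0, this comparison says nothing about chance for the genes outside the list, such as H3c14. Chance cannot be excluded for the number of gene lists past the camera threshold: 29 of 35 splits gave 8 or more, and the highest of the others gave 27, several times the real number. Whether this comes from a structure of the samples unrelated to genotype or from the preset correlation of 0.01 was not tested. With an estimated correlation 0 lists passed in the real grouping.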

How the results depend on the processing

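All settings were fixed before the data were examined except the fits without wild-type 2 and knockout 2, those without these and wild-type 6, those with 2 surrogate variables and the merged H3 pair. Gpihbp1 kept its direction and its call in 22 alternatives, with log2 fold changes from -13.72 to -10.90 and an adjusted p of at most 0.0412, and glmTreat also called it. Against 4 genes, 3 higher and 1 lower, DESeq2 called 8 with 4 lower (349 genes had no adjusted p). Leave-one-out fits called 2 to 3 genes, 1 to 2 of them higher. With 1 or with 2 surrogate variables 2 genes were lower, and without wild-type 2, knockout 2 and wild-type 6 there were 1 higher and 2 lower. RLE, total-count and strict-filter fits gave 3 genes, all among the 4, and upper-quartile, limma-voom, unfiltered, glmTreat and non-robust fits 3 to 5. Psca also did not pass with quality weights (adjusted p = 0.478) or without the 3 libraries (0.201). Total-count scaling moved the median log2 fold change of all genes by 0.10. Against 8 lists, an estimated correlation gave 0, fry 1, 1 surrogate variable 18, 2 surrogate variables 25, the fit without the 3 libraries 20, RLE 7, total counts 12, no filter 11 of 50 tested, the strict filter 6 of 45, and leave-one-out fits 8 to 18. Another 8, not all the same lists, came without wild-type 2 and knockout 2. Total counts added erythroid and platelet, glycolysis, citric acid cycle, adipocyte and immediate early lists, and moved the means of oxidative phosphorylation to -0.34 and PPARα targets to -0.23; no filter added lymphocyte, thymus, adipocyte and muscle atrophy lists and gave neutrophil markers a mean of 2.20. Without wild-type 2 and knockout 2, cholesterol synthesis (adjusted p = 0.889), interferon response (0.0596) and Schwann cell markers (0.0596) did not pass, and without wild-type 6 as well cholesterol synthesis (0.746), ribosomal proteins (0.743) and clock genes (0.0529) did not. The causes were not tested. Removal of mitochondrially encoded genes could not be run, as 0 were listed.

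The groups share only the numbers 2 and 4, with deviation correlations of 0.908 and 0.110 (hearts with different numbers -0.671 to 0.685), and no source says that a number pairs hearts. With a replicate block, 168 genes were called, 93 higher and 75 lower, including all 4, and 24 lists; this fit leaves 1 residual degree of freedom. Log2 fold changes there took the other sign for Angptl4 (-0.18), Ucp3 (0.022), Cpt1b (0.052), Nppa (0.36), Nppb (0.087) and the mean of PPARα targets (0.039, adjusted p = 0.752), and Pdk4 had -0.073. There beta-oxidation (0.31, adjusted p = 0.00459) and adult sarcomere genes (0.29, 0.0164) passed with the other sign, 2 of 4 lists that did.

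The 22 genes fixed beforehand that were tested gave 478 further values, of which 395 kept direction and side, 1 newly passed and 82 took the other sign, with 0 of these 82 past the threshold. Outside the block these were, on the log2 scale, with RLE and DESeq2 Cd36 at -0.014; with limma-voom Angptl4 -0.86, Plin2 -0.16, Nppb 0.057 and Col3a1 -0.14; with quality weights Angptl4 -1.85, Ucp3 0.30, Cpt1b 0.0030, Plin2 -0.41, Nppb 0.18, Col1a1 -0.43, Col3a1 -0.83 and Cd68 -0.46. With 1 surrogate variable they were Angptl4 -1.69, Ucp3 0.0053, Plin2 -0.25, Col1a1 -0.015, Col3a1 -0.56 and Cd68 -0.31, and with 2 Angptl4 -0.19, Ucp3 0.068, Cd36 -0.082, Plin2 -0.036, Nppa 0.32, Nppb 0.20, Col1a1 -0.068 and Col3a1 -0.31. Without wild-type 2 and knockout 2 they were Angptl4 -2.07, Cd36 -0.045, Plin2 -0.43, Nppb 0.25 and Col3a1 -0.26, and without wild-type 6 as well Angptl4 -0.88, Cd36 -0.23, Plin2 -0.27, Nppa 0.34, Nppb 0.57, Col1a1 -0.28, Col3a1 -0.37 and Gdf15 0.020. Of the 8 lists that passed, those whose mean changed sign or direction in these fits were oxidative phosphorylation, at 0.18 without the 3 libraries and 0.065 with 2 surrogate variables, and ribosomal proteins, at -0.028 without the 3 libraries and on the other side of the remaining genes.

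Leave-one-out ranges that crossed 0, among genes named beforehand and the 8 lists, were Angptl4 -3.21 to 1.24, Ucp3 -0.79 to 0.11, Cd36 -0.21 to 0.20, Slc2a1 -0.14 to 0.88, Plin2 -0.66 to 0.34, Nppa -2.84 to 0.15, Nppb -0.63 to 0.67, Acta1 -0.57 to 1.17, Ankrd1 -0.43 to 1.07, Myh6 -0.082 to 0.63, Col1a1 -2.43 to 3.43, Col3a1 -2.82 to 2.78, Postn -3.45 to 2.59, Gdf15 -2.42 to 2.24, Cd68 -1.82 to 1.96, oxidative phosphorylation -0.80 to 0.070 and interferon response -0.23 to 0.62. The mean of 32 of the 38 other lists crossed 0 as well. Differences between groups ranged from -585533 to 922402 total counts, from -10.8 to 236 detected genes and from -0.822 to 1.69 percentage points for the 10 most abundant genes. Depth and spread left changes of 2-fold mostly undetected in the simulation, so genes that did not pass are not shown to be unchanged. Larger changes can be missed as well. More genes were called in the simulation than in the real comparison, which let larger unadjusted p-values pass there.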

Other observations

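The genes in this part, and the fits with 2 surrogate variables and without the libraries that stood apart, were chosen after the values were seen. Fbp2, the muscle form of the gluconeogenic enzyme fructose bisphosphatase, was lower in every knockout heart than in every wild-type heart. It stood at 13.03, 32.9, 33.4 and 60.9 CPM in wild-type 2, 4, 5 and 6 and at 6.28, 2.17, 8.32 and 6.03 CPM in knockout 1, 2, 3 and 4. Its log2 fold change was -2.62 with a standard error of 0.52 and it did not pass (edgeR unadjusted p = 0.000592, adjusted p = 0.99998). It passed in 5 of 23 other settings. Those fixed beforehand were DESeq2 (adjusted p = 0.00132), 1 surrogate variable (0.00155) and the replicate block (6.77e-13), which leaves 1 residual degree of freedom. The others were 2 surrogate variables (0.00109) and the fit without wild-type 2, knockout 2 and wild-type 6 (0.0473). Over all settings the adjusted p reached 0.99998, and log2 fold changes ran from -2.90 to -2.21. The acyl-CoA thioesterase gene Acot1, a PPARα target, had -2.02 with a standard error of 0.63 (edgeR unadjusted p = 0.00975, adjusted p = 0.99998), at 19.6 ± 13.46 CPM in the wild type and 4.84 ± 1.38 in the knockout (SD, n = 4 each), and it passed in 0 of 23 other settings, with adjusted p-values from 0.169 to 0.99998 and log2 fold changes from -2.38 to -0.82.

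The clock genes Ciart and Dbp were, in knockout 2, within the range of the wild type, unlike in the other knockout hearts. Ciart stood at 1.74, 2.47, 4.02 and 3.65 CPM in wild-type 2, 4, 5 and 6 and at 18.5, 2.63, 14.2 and 10.5 CPM in knockout 1, 2, 3 and 4, and Dbp at 18.6, 35.4, 91.1 and 73.1 against 170, 45.6, 143 and 95.3 CPM. For the clock genes Per2 and Arntl, knockout 4 as well as knockout 2 was within the range of the wild type. Per2 stood at 16.9 and 17.6 CPM in knockout 2 and 4, against 5.78 to 26.8 in the wild type. Arntl stood at 10.2 and 14.4 CPM in knockout 2 and 4, against 9.84 to 25.6 in the wild type. The hour at which each heart was taken is not given in the labels. Wild-type 2 and knockout 2 shared further genes that were lower in the other 6 libraries. Tnc, a matrix protein of tissue repair, stood at 604 and 585 CPM against 0.786 to 1.97 in the other 6 libraries, Timp1 at 572 and 758 against 1.66 to 23.0, Spp1 at 379 and 756 against 0 to 1.55, and the proliferation gene Mki67 at 62.3 and 62.1 against 0.979 to 6.03. Myh6 was lowest in these 2 hearts, at 6904 and 8808 CPM against 16257 to 33826. In wild-type 6 the atrial genes Myl7 and Sln stood at 427 and 356 CPM, against 0 to 0.489 and 0 to 0.196 in the other 7 libraries, and its TMM factor of 0.678 was the lowest.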
